A study of Homo sapiens with 6 samples.

How the data were processed

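Gene expression was measured with Affymetrix Human Gene 1.0 ST arrays, one array per sample, in 6 samples of HepG2 cells, a human liver cancer cell line that keeps many hepatocyte functions. Per the labels' protocols, lentiviruses carried either a short hairpin RNA against PARP-2 or a scrambled hairpin at a multiplicity of infection of 40. Total RNA with an integrity number above 9.0 was used, 250 ng of it was amplified and labelled, and hybridisation ran at 45 °C for 16 h. The labels put 3 arrays in the PARP-2 shRNA group and 3 in the scrambled shRNA group. They do not say whether the samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Nor do they say how many hairpins were used.

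The deposited values are log2 expression values, 1 per probe set, made by the authors with RMA (background correction, quantile normalization between arrays and summary of probes), per the submitters' processing notes. The software and version are not given in the sources used here. The log base was read from the values, which ran from 1.40 to 14.5 with no missing entries. RMA makes the distributions of probes equal between arrays, so a shift shared by most transcripts cannot be seen in these values. The array medians over all probe sets were 7.40, 7.41 and 7.49 in the scrambled arrays and 7.35, 7.32 and 7.33 in the PARP-2 shRNA arrays. For arrays the number of arrays limits the precision, and with 3 per group the median standard error of a log2 difference was 0.063.

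Of 33297 probe sets, 19460 were annotated to exactly 1 gene symbol, 1754 to several symbols and 12083 were not in the annotation table. Gene numbers of 19429 of the single-symbol probe sets were found in the human reference gene table, and 0 symbols changed. No gene was named from a probe set with several symbols. Each gene was represented by 1 probe set, and for the 769 genes with more than 1 the brightest over all 6 arrays was taken, which gave 18417 genes. The 95th percentile of 338 olfactory receptor genes, most of which were taken to be silent in liver cells, served as a background level. It lay at 6.77 on the log2 scale. By mean value, 13029 genes lay above this level and 5388 at or below it.

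The comparison was PARP-2 shRNA minus scrambled shRNA. It was fitted with limma 3.58.1 (lmFit and eBayes, no trend, not robust) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. PARP2 was also tested with a two-sided exact permutation of its 6 values. Of 39 gene lists, 38 with at least 5 measured members were tested with camera from limma at its preset correlation of 0.01, adjusted over the lists; the list of mitochondrially encoded genes had 0 of 12 members among the genes and was not tested. The number of members past the threshold was counted with p adjusted over all genes and adjusted over the list alone. Each list's median was also placed among 10000 random lists of the same size, matched on mean value. The groups, lists, tests and alternatives were fixed before the data were examined. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

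Genes were named by a rule. It took PARP2 and the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold whose groups did not overlap, leaving out unnamed, predicted, open reading frame, microRNA, snoRNA, olfactory receptor and pseudogene entries. It added SREBF1, SREBF2, ABCA1, APOA1, SIRT1 and PARP1 whatever their values, the 4 members with the smallest p of each list past the threshold and the 2 of each other list. Some genes of the fixed set are not reported here. A gene named outside the rule is marked as such, except under other observations, where members of the lists and tests used there are named.

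The alternatives were a variance prior with trend and robust fitting, a further quantile normalization, equal array medians, 2 filters on dim genes, the mean of a gene's probe sets, all probe sets as rows, the replicate number as a block, array weights, each array left out in turn, other thresholds, a variance estimated per gene alone, and for lists an estimated correlation, fry, ranks and lists without members at background. The fit was tested on simulated data built on the 18417 genes of this comparison, with 200 of them changed. These 200 were drawn from the genes above the background level, so the rates do not cover dimmer genes. It called 53.7% of the genes changed by 0.3 on the log2 scale, 88.1% of those changed by 0.5 and 97.0% of those changed by 1, and 4.79% of its 167 calls were false. A list shifted by 0.2 was recovered with a median of 0.19, and 0 of the other lists were called. Genes were simulated independently of each other, so this cannot show how often camera falsely calls lists of correlated genes.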

Results

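Expression was compared between HepG2 cells that received a lentiviral hairpin against PARP-2, a DNA-damage-activated ADP-ribosyltransferase, and HepG2 cells that received a scrambled hairpin, with 3 arrays per group. The comparison asks which transcripts differ when PARP-2 is depleted. Arrays of the same group correlated at 0.997 to 0.998 across genes and arrays of different groups at 0.992 to 0.994, where genes are not independent replicates. No pair of arrays was a duplicate. The first principal component held 63.6% of the variance and separated the groups, and the second held 14.0%.

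PARP2 itself (probe set 7973036) was lower in all 3 arrays of the PARP-2 shRNA group. Its log2 value was 10.30 ± 0.03 (SD, n = 3) with the scrambled hairpin and 9.61 ± 0.03 (SD, n = 3) with the PARP-2 hairpin. The difference of -0.68 (SE 0.047, limma adjusted p = 1.06e-04) left 62.25% of the scrambled level. The exact two-sided permutation test gave p = 0.10, the smallest value 3 against 3 arrays allow. PARP1, the main enzyme of the family, rose by 0.33 (SE 0.059, limma adjusted p = 0.0079). Of the 19 measured genes of the PARP family list, 4 rose and 1, PARP2, fell (4 and 2 adjusted over the list alone). The list did not pass camera (adjusted p = 0.84; median -0.0061, mean 0.00012). The hairpin's effects on targets other than PARP2 cannot be separated from those of PARP-2 loss in this design.

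**Figure D1:**
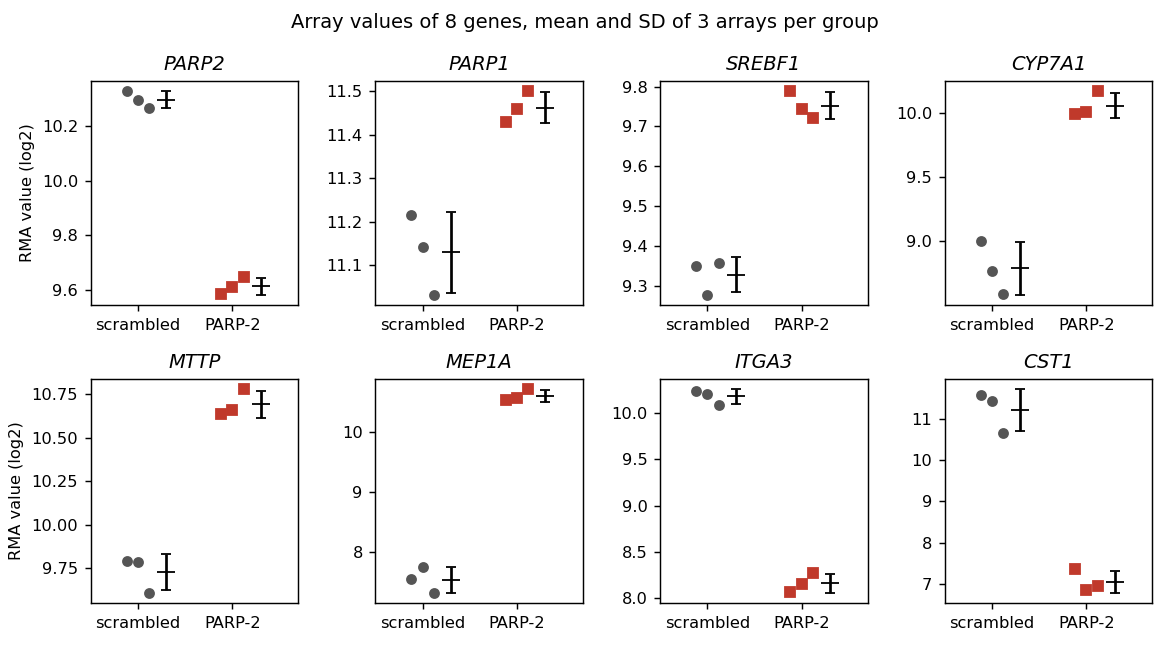
Log2 RMA values of 8 genes in each array, with scrambled shRNA as grey circles, PARP-2 shRNA as red squares, and the mean and SD of 3 arrays as a black bar; each panel has its own vertical axis, which does not start at 0. The groups do not overlap in any panel, and PARP2, ITGA3 and CST1 are lower with the PARP-2 hairpin.

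Of 18417 genes, 3348 (18.2%) passed the threshold in limma, 1877 higher and 1471 lower with the PARP-2 hairpin. Most differences were small, with a median size of 0.31 on the log2 scale. Among the larger ones falls were more numerous: 145 genes rose and 290 fell by 1.5-fold or more, and 36 rose and 70 fell by 2-fold or more. The groups did not overlap for 3347 of the 3348 genes, and for 37.1% of all genes, where chance gives 10%. The share of higher genes among the calls depended on the scaling. It was 56.1% as deposited, 69.0% (2868 higher, 1289 lower) after a further quantile normalization and 83.2% (4434 higher, 898 lower) with array medians set equal. A fit over all probe sets, which is no other scaling, called 1562 probe sets higher and 2484 lower, of which 1286 and 1125 had 1 gene symbol. Equal array medians added the same amount to the difference of every gene and moved the median difference of all genes from 0.018 to 0.12. The medians set equal were those of all 33297 probe sets, including the 12083 that were not annotated. The latter had a median difference of -0.057, against 0.017 for probe sets with 1 symbol. Without PARP-2 shRNA replicate 2 the counts were 1027 higher and 934 lower. Without PARP-2 shRNA replicate 1 or scrambled shRNA replicate 2, 1170 and 1174 genes were higher.

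The largest rise was that of MEP1A, a subunit of the metalloprotease meprin A, which was 8.42-fold higher (log2 difference 3.07, SE 0.11, limma adjusted p = 8.26e-06). CP, the plasma copper carrier ceruloplasmin, rose 3.52-fold. SLC38A4, an amino acid transporter, and SLCO4C1, an organic anion transporter, rose 3.34-fold and 3.14-fold. The scrambled mean of SLC38A4, 6.58, lay below the background level. The other large rises were BPIFB2 (1.62 on the log2 scale), the vault RNA VTRNA1-2 (1.60), the secreted liver protein FGL1 (1.56), TOX3 (1.55), the extracellular glycoprotein reelin (RELN, 1.51) and PLPPR1 (1.41).

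The largest fall was that of CST1, a secreted inhibitor of cysteine proteases, from 11.2 ± 0.50 to 7.05 ± 0.27 (SD, n = 3). CST1 shares much of its sequence with CST2 and CST4, whose probe sets differed by -0.70 and -0.57 (both named outside the rule, for this check), so the values of the 3 genes are uncertain. CHI3L1, a secreted chitinase-like protein, fell 6.89-fold (log2 difference -2.79, SE 0.14). Genes of the cell surface and matrix were among the other falls, with SPARC, a matrix-associated glycoprotein, at -2.06 and ITGA3, the alpha-3 subunit of laminin-binding integrin, at -2.02. SYTL2 differed by -2.28, with a PARP-2 shRNA mean of 5.37, below the background level. The remaining falls were those of KLK6, a secreted serine protease (-1.98), ANXA1 (-1.97), EDN1, which encodes the precursor of endothelin-1 (-1.96), TNFRSF9 (-1.90) and AHNAK2 (-1.88). All 20 of these genes, picked for their large differences on these same arrays, kept their calls when any 1 array was left out.

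**Figure D2:**
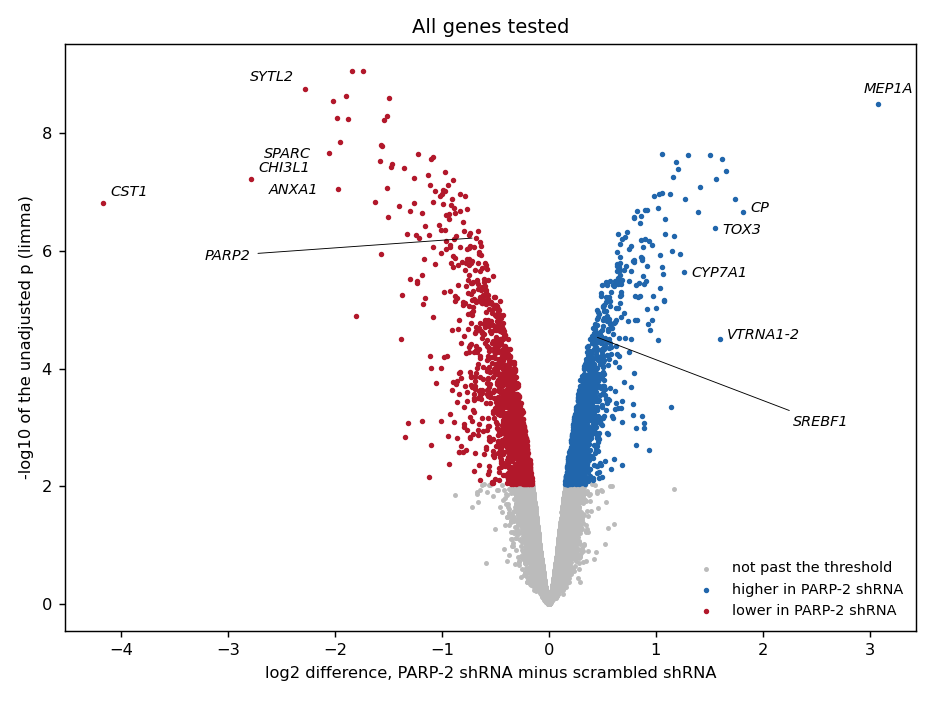
Each point is 1 of 18417 genes, with the log2 difference (PARP-2 shRNA minus scrambled shRNA) on the horizontal axis and -log10 of limma's unadjusted p on the vertical axis; genes higher past the threshold are blue, genes lower are red and the rest are grey. The falls reach farther from 0 than the rises, apart from MEP1A at 3.07.

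Genes of cholesterol biosynthesis rose together. Of 17 measured members, 15 rose and 0 fell, also adjusted over the list alone, with a median log2 difference of 0.30. They included FDPS, which makes farnesyl diphosphate (0.59, SE 0.065), CYP51A1, the lanosterol demethylase (0.55, SE 0.062), MSMO1 (0.40) and NSDHL (0.39). camera gave the list an adjusted p of 2.39e-08, and the adjusted p was 0.099 with an estimated correlation. SREBF1, which encodes a transcription factor of lipid synthesis, rose by 0.42 (SE 0.049, limma adjusted p = 0.0012). SREBF2, which encodes its sterol-regulated relative, differed by 0.10 (SE 0.054, limma adjusted p = 0.25) and passed the threshold only under equal array medians among its alternatives (0.20, limma adjusted p = 0.047). The list of sterol uptake and SREBP regulation moved both ways. Of its 14 measured genes 4 rose and 3 fell (5 and 3 adjusted over the list alone), among them the lipoprotein receptor VLDLR at -0.59 (camera adjusted p = 0.97; median 0.037, mean -0.0096). Leaving out any 1 array, or a further quantile normalization, gave 2 higher genes, and array medians set equal gave 6 higher and 2 lower.

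Of 23 measured genes of fatty acid and triglyceride synthesis, 15 rose and 2 fell, also adjusted over the list alone, with a median of 0.24. ELOVL6, a fatty acid elongase, rose by 0.84, MID1IP1, an activator of acetyl-CoA carboxylase, by 0.75, the desaturase FADS2 by 0.66 and LPIN1, a phosphatidate phosphatase, by 0.49. The list passed camera with an adjusted p of 7.12e-05, and the adjusted p was 0.099 with an estimated correlation. Of 16 measured genes of cholesterol efflux and HDL, 8 rose and 0 fell (10 and 0 adjusted over the list alone), with a median of 0.23. The endothelial lipase LIPG rose by 0.77, the sterol transporter ABCG8 by 0.46 and the sterol acyltransferases SOAT2 and SOAT1 by 0.46 and 0.24. The list thus holds a lipase and acyltransferases besides transporters, so its rise does not show that efflux rose. APOA1, the main protein of HDL, rose by 0.33 (SE 0.061, limma adjusted p = 0.0093). ABCA1, which loads cholesterol onto APOA1, differed by -0.016 (SE 0.048, limma adjusted p = 0.87), and its sign turned with array medians set equal (0.082). The list's camera adjusted p was 5.30e-04, and the adjusted p was 0.099 with an estimated correlation. Only 5 of its genes rose without PARP-2 shRNA replicate 1 or 2.

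Of 18 measured genes of bile acid synthesis and transport 6 rose and 1 fell (11 and 1 adjusted over the list alone), with a median of 0.20. CYP7A1, the rate-limiting enzyme of bile acid synthesis, rose 2.41-fold (log2 difference 1.27, SE 0.10, limma adjusted p = 2.37e-04). The side-chain oxidase ACOX2 rose by 0.77 and NR0B2, a nuclear receptor that represses CYP7A1, by 0.43, while the bile acid exporter subunit SLC51A differed by -0.39. camera gave an adjusted p of 5.10e-04, and the adjusted p was 0.099 with an estimated correlation. With array medians set equal, 13 members were higher. Of 13 measured genes of apolipoproteins and VLDL secretion, 5 rose and 1 fell, also adjusted over the list alone. MTTP, which loads lipid onto apolipoprotein B, rose by 0.96 and APOM by 0.81. The list did not pass (camera adjusted p = 0.073, median 0.058), and 3 members rose without PARP-2 shRNA replicate 2 or 3 or scrambled shRNA replicate 2 or 3. It passed without PARP-2 shRNA replicate 3 (camera adjusted p = 0.032) and without scrambled shRNA replicate 1 (0.021), with array weights (0.049) and over all probe sets (0.015).

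Of 25 measured genes of fatty acid oxidation and PPAR targets 11 rose and 1 fell (13 and 2 adjusted over the list alone), with a median of 0.17. PPARGC1A, a coactivator of mitochondrial genes, rose 2.01-fold. ACAA2 and EHHADH, enzymes of beta-oxidation, rose by 0.44 and 0.38 and the nuclear receptor PPARG by 0.31. camera gave an adjusted p of 7.79e-04, and the adjusted p was 0.18 with an estimated correlation. The higher members numbered 7 without replicate 2 of either group. Of 14 measured genes of the citric acid cycle, 7 rose and 0 fell, also adjusted over the list alone, with a median of 0.17. IDH3A rose by 0.38, PDHB by 0.29, SUCLA2 by 0.21 and SUCLG2 by 0.20. That list passed camera with an adjusted p of 0.0057, and the adjusted p was 0.18 with an estimated correlation and 0.15 after a further quantile normalization. Its count fell to 1 without PARP-2 shRNA replicate 1, to 2 without PARP-2 shRNA replicate 2 or scrambled shRNA replicate 2, and to 3 without any 1 of the other 3 arrays; PDHB, SUCLA2 and SUCLG2 each lost the threshold in some of these fits.

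Other lists of energy metabolism did not pass camera. Of 36 measured genes of oxidative phosphorylation 4 rose and 0 fell (0 and 0 adjusted over the list alone), with ATP5F1A at 0.32 and ATP5MC3 at 0.19 (camera adjusted p = 0.11, median 0.067). With 1 array left out, 0 to 2 genes of the list were higher, and without scrambled shRNA replicate 1 the list itself passed (camera adjusted p = 0.0079), as it did over all probe sets (0.010). Its higher genes numbered 12 with array medians set equal, 9 with the trend and robust prior and 8 among genes above the background level. Of 20 genes of mitochondrial biogenesis 3 rose and 1 fell (3 and 2 adjusted over the list alone), with MFN2 at 0.27 and TFAM at 0.25 (camera adjusted p = 0.065, median 0.095). Its camera adjusted p was 0.016 without scrambled shRNA replicate 1, 0.024 on ranks and 0.0073 over all probe sets. With array medians set equal 10 of its genes were higher and 0 lower, and with the trend and robust prior 7 and 2. The TFAM call was kept only without PARP-2 shRNA replicate 1 among the 6 fits with 1 array left out, the 1 fall in none of them, and 1 of its genes rose without PARP-2 shRNA replicate 2 or scrambled shRNA replicate 2 or 3. Of 20 genes of sirtuins and NAD metabolism 3 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.64, median 0.0084). SIRT1 rose by 0.24 (SE 0.054, limma adjusted p = 0.018) and SIRT2 by 0.29; the SIRT1 call was lost without PARP-2 shRNA replicate 2 (limma adjusted p = 0.051) or 3 (0.055) or scrambled shRNA replicate 2 (0.068). The list had 1 higher gene without PARP-2 shRNA replicate 2 or 3, and its lower gene lost the threshold whichever array was left out. It had 7 higher and 0 lower with array medians set equal and 6 and 1 after a further quantile normalization. Of 22 genes of glycolysis and gluconeogenesis 7 rose and 3 fell (8 and 3 adjusted over the list alone). PCK1, the entry enzyme of gluconeogenesis, rose 2.08-fold and the glucose transporter SLC2A1 differed by -0.79 (camera adjusted p = 0.28, median 0.036).

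Of 30 measured S phase and replication genes 13 rose and 0 fell (18 and 0 adjusted over the list alone), with a median of 0.16. The replication licensing factor CDC6 rose by 0.68, its partner CDT1 by 0.33, MCM10 by 0.29 and TYMS by 0.24. camera gave an adjusted p of 6.21e-06, and the adjusted p was 0.14 with an estimated correlation. Only 6 members rose without replicate 2 of either group, and 8 without replicate 3 of either group. Of 31 measured G2/M and mitosis genes 11 rose and 0 fell (17 and 0 adjusted over the list alone), with a median of 0.18. DLGAP5 rose by 0.36, BIRC5 and the checkpoint kinase BUB1 by 0.33 each and CDC25C by 0.32. This list passed camera with an adjusted p of 5.47e-05, and the adjusted p was 0.34 with an estimated correlation. Without PARP-2 shRNA replicate 1, 5 of its members rose, and without scrambled shRNA replicate 2, 6 rose. With array medians set equal, 22 S phase and 18 G2/M genes were higher.

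Base excision and single-strand break repair, the pathway in which PARP-2 acts, had 7 of 21 measured genes higher and 1 lower, also adjusted over the list alone, with a median of 0.15. NTHL1 rose by 0.39, FEN1 by 0.30 and the uracil glycosylase UNG by 0.27, and SMUG1, also a uracil glycosylase, differed by -0.26. The SMUG1 call was lost with array medians set equal (limma adjusted p = 0.085). camera gave the list an adjusted p of 0.012, and the adjusted p was 0.16 with an estimated correlation and 0.052 among genes at or above the median level. Its higher genes numbered 3 without PARP-2 shRNA replicate 2, 4 without PARP-2 shRNA replicate 3 or scrambled shRNA replicate 2 or 3, and 14 with array medians set equal. Homologous recombination and Fanconi genes showed 2 of 24 higher and 2 lower (3 and 2 adjusted over the list alone), with BRIP1 at 0.31 and ATM at -0.30 (camera adjusted p = 0.84, median 0.0040). With 1 array left out, 1 or 2 were higher and 0 or 1 lower, while array medians set equal gave 7 and 0 and a further quantile normalization 5 and 1. The ATM call was lost without PARP-2 shRNA replicate 1 or 2 (limma adjusted p = 0.069 and 0.074) or scrambled shRNA replicate 1 or 3 (0.056 and 0.064). Of 23 p53 targets 0 rose and 6 fell, also adjusted over the list alone, with PLK3 at -0.47 and the cell cycle inhibitor CDKN1A at -0.41. That list did not pass (camera adjusted p = 0.089), and its median of 0.00047 had the opposite sign to its mean of -0.068. It passed after a further quantile normalization (camera adjusted p = 0.0039) and among genes at or above the median level (0.044), and with array medians set equal 3 of its genes were lower.

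Of 19 measured coagulation factor genes 12 rose and 1 fell (14 and 1 adjusted over the list alone), with a median of 0.26. HRG rose by 0.90, kininogen (KNG1) by 0.86, SERPINF2, the inhibitor of plasmin, by 0.67 and F11 by 0.43. The scrambled mean of HRG, 6.25, lay below the background level and its PARP-2 shRNA mean, 7.16, above it. camera gave an adjusted p of 6.21e-06, and the adjusted p was 0.099 with an estimated correlation. Of 23 measured acute phase and complement genes 12 rose and 3 fell, also adjusted over the list alone, with a median of 0.17. The complement component C5 rose by 0.88 and the fibrinogen chains FGA and FGG by 0.80 and 0.75. HP, haptoglobin, rose by 1.23, but HPR, which is nearly identical in sequence and was named outside the rule for this check, rose by 1.06, so the pair is uncertain. This list passed camera with an adjusted p of 0.0081, and the adjusted p was 0.31 with an estimated correlation, 0.056 after a further quantile normalization, 0.051 with array medians set equal and 0.062 on ranks.

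Of 24 measured genes of hepatocyte and hepatoblast identity 11 rose and 1 fell (12 and 2 adjusted over the list alone), with a median of 0.17. DLK1, a hepatoblast surface protein, rose 2.63-fold, transthyretin (TTR) 1.89-fold and the histidine ammonia-lyase HAL 1.49-fold. ARG1, the last enzyme of the urea cycle, rose by 0.85 with both group means below the background level. camera gave an adjusted p of 6.42e-05, and the adjusted p was 0.099 with an estimated correlation. Xenobiotic metabolism moved both ways, with 5 of 21 genes higher and 5 lower, also adjusted over the list alone (camera adjusted p = 0.57; median -0.0033, mean 0.087). The efflux pump ABCB1 rose 2.47-fold and the glucuronosyltransferase UGT2B4 1.73-fold. Its lower genes numbered 2 without PARP-2 shRNA replicate 2 and 3 without PARP-2 shRNA replicate 1, and with array medians set equal it had 9 higher and 2 lower.

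Of 26 genes of the unfolded protein and amino acid response 10 rose and 0 fell (14 and 0 adjusted over the list alone), with a median of 0.15. PHGDH, the first enzyme of serine synthesis, rose by 0.50, the endoplasmic reticulum chaperones DNAJB9 and DNAJC3 by 0.50 and 0.40 and the transcription factor XBP1 by 0.35. camera gave an adjusted p of 1.97e-04, and the adjusted p was 0.23 with an estimated correlation. Only 6 members rose without PARP-2 shRNA replicate 1 or 2 or scrambled shRNA replicate 2, and 16 were higher with array medians set equal. The probe sets of ATF4, a member named outside the rule for this check, disagreed. The brighter one, which was used, was at 0.19 and did not pass. The other was at -0.59 and passed in the fit over all probe sets (limma adjusted p = 0.025), so the value of ATF4 is uncertain.

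Of 18 measured immediate early genes, which growth signals induce within minutes, 2 rose and 9 fell (2 and 11 adjusted over the list alone), with a median of -0.33. DUSP1, a MAP kinase phosphatase, fell by 0.88, CCN1 by 0.83 and JUNB by 0.63 on the log2 scale, while JUND rose by 0.67. EGR1, named after its values were seen, was at -1.39. camera gave an adjusted p of 6.42e-05, and the adjusted p was 0.34 with an estimated correlation. Of 8 measured genes of the metallothionein list, which holds a zinc transporter too, 0 rose and 2 fell (0 and 5 adjusted over the list alone), with a median of -0.16. MT1F fell by 0.57 and the zinc exporter SLC30A1 by 0.24 on the log2 scale, and MT1G and MT1E, which did not pass, were at -0.29 and -0.17. This list's camera adjusted p was 4.77e-04, and the adjusted p was 0.29 with an estimated correlation. The metallothioneins share much of their sequence, so the values of single members are uncertain, and the SLC30A1 call was lost with array medians set equal (limma adjusted p = 0.086), a setting with 1 lower member. The lower members numbered 4 after a further quantile normalization, with the trend and robust prior or above the background level, and 5 with array weights or at or above the median level.

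Of 18 measured genes of the epithelial-mesenchymal transition list 1 rose and 6 fell (1 and 11 adjusted over the list alone), with a median of -0.16. The falls mixed both sides of the transition: SPARC and TGFB2 (-1.17, PARP-2 shRNA mean 6.13, below the background level) mark or drive the mesenchymal state, while E-cadherin (CDH1, -0.56) is epithelial. The other 3 falls, named after their values were seen, were the epithelial genes EPCAM (-0.42) and KRT19 (-0.29) and the growth factor TGFB1 (-0.41). The other probe set of EPCAM was at -0.21 and did not pass. CLDN1, a tight junction gene, rose by 0.27. camera gave an adjusted p of 1.25e-04, and the adjusted p was 0.16 with an estimated correlation. The trend and robust prior and array weights each gave 10 lower members.

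**Figure D3:**
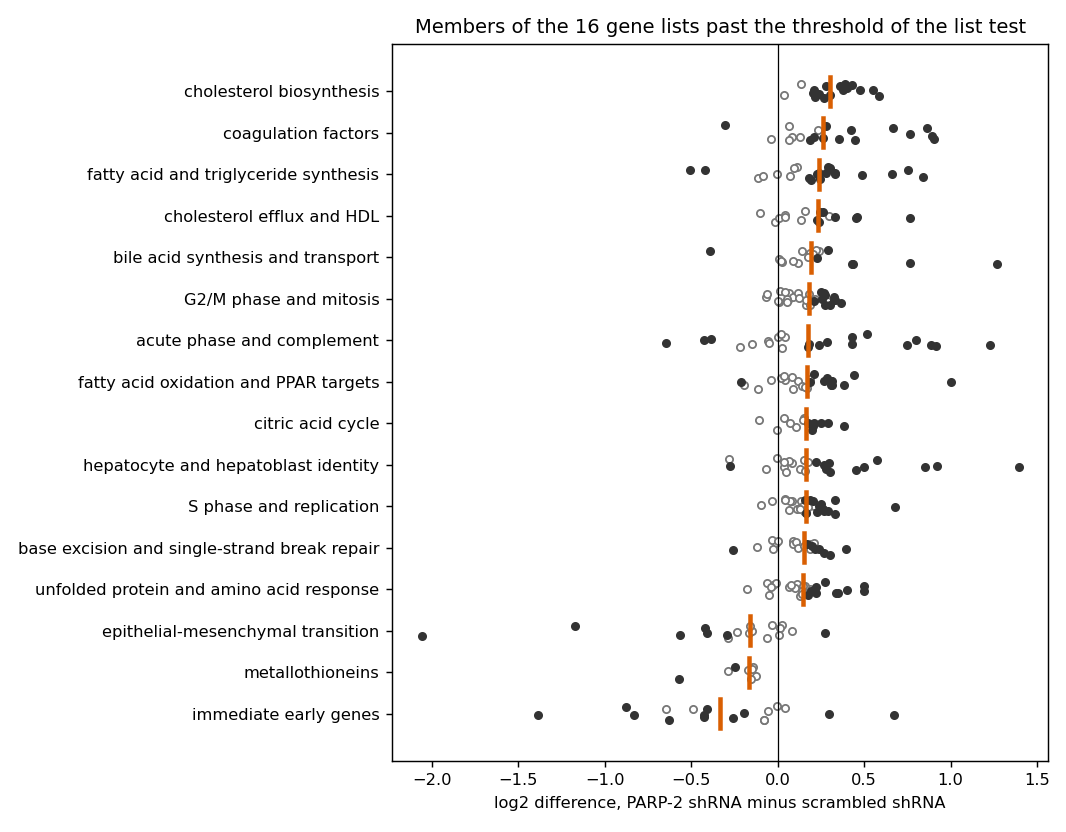
Log2 differences (PARP-2 shRNA minus scrambled shRNA, horizontal axis) of the measured members of the 16 lists past the threshold of camera, 1 list per line; filled points are genes past the limma threshold, open points are not, and the orange bar is the list's median. Medians run from -0.33 for immediate early genes to 0.30 for cholesterol biosynthesis.

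The lists of type I interferon, NF-kB, NRF2, hypoxia and heat shock genes did not pass camera. Type I interferon genes, which cells induce on sensing viral nucleic acid, had 5 of 26 higher and 1 lower (6 and 2 adjusted over the list alone), with IFIT5 at 0.77 and USP18 at 0.56 (camera adjusted p = 0.52, median 0.051). Without any 1 of the scrambled arrays 3 genes of the list were higher, and with array medians set equal 8 were higher and 0 lower. NF-kB and inflammation genes had 3 of 20 higher and 5 lower (4 and 5 adjusted over the list alone), with CXCL8 at -0.78 and CCL20 at 0.64 (camera adjusted p = 0.19, median -0.030). Its higher genes numbered 1 without PARP-2 shRNA replicate 2 or scrambled shRNA replicate 3. Genes of the NRF2 oxidative stress response had 1 of 21 higher and 4 lower (2 and 6 adjusted over the list alone), with HMOX1 at -0.53 and ABCC3 at -0.39 (camera adjusted p = 0.43; median 0.017, mean -0.037). The 1 higher gene lost the threshold whichever array was left out, and the list passed after a further quantile normalization (camera adjusted p = 0.036). With array medians set equal it had 4 higher and 3 lower. Hypoxia genes had 3 of 14 higher and 4 lower, also adjusted over the list alone, with NDRG1 at -1.13 and P4HA2 at -0.39 (camera adjusted p = 0.43, median -0.020), and 6 higher and 3 lower with array medians set equal. Heat shock genes had 2 of 12 higher and 1 lower (5 and 1 adjusted over the list alone), with HSP90AA1 at 0.24 and HSPB1 at -0.30 (camera adjusted p = 0.57, median 0.0045). The HSPB1 call was lost with array medians set equal (limma adjusted p = 0.054), which gave 5 higher and 0 lower. In this list 0 genes were higher without PARP-2 shRNA replicate 1 or scrambled shRNA replicate 2 and 1 without replicate 3 of either group or PARP-2 shRNA replicate 2.

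Housekeeping lists and markers of other cell types did not pass camera either. Of 18 ribosomal protein genes 1, RPL13, rose (0.34; 0 adjusted over the list alone), and RPS3 was at 0.14 (camera adjusted p = 0.31, median 0.049). With array medians set equal 4 ribosomal protein genes and 3 reference genes were higher. Of 9 reference genes 1, HPRT1, rose (0.27; 1 adjusted over the list alone), and SDHA was at 0.13 (camera adjusted p = 0.91; median -0.0085, mean 0.025). The HPRT1 call was lost without PARP-2 shRNA replicate 2 (limma adjusted p = 0.065) or 3 (0.050) or scrambled shRNA replicate 2 (0.061), and the RPL13 call without PARP-2 shRNA replicate 2 or 3 or scrambled shRNA replicate 2 or 3 (0.058 to 0.099). In the small RNA pathway, which processes hairpins, 0 of 13 genes rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.43, median -0.0045). These were AGO2 (-0.43) and AGO3 (-0.36), and AGO3 lost the threshold without PARP-2 shRNA replicate 2 (limma adjusted p = 0.060). With array medians set equal 3 genes of this list were higher and 2 lower, and among genes at or above the median level 2 and 4.

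Of 12 fibroblast and stellate markers 1 rose and 4 fell, also adjusted over the list alone, with PDGFRB at 0.54 and COL1A1 at -0.34 (camera adjusted p = 0.43; median 0.017, mean -0.0094). With any 1 array left out, 1 or 2 genes of the list were lower, and the balance turned with array medians set equal (3 higher, 1 lower) and was even after a further quantile normalization (2 and 2). Of 11 leukocyte markers 2 rose and 0 fell (3 and 0 adjusted over the list alone), with lysozyme (LYZ) at 0.47 and CD79A at 0.23 (camera adjusted p = 0.31, median 0.031). CD79A lost the threshold without any 1 array other than scrambled shRNA replicate 1 (limma adjusted p = 0.051 to 0.14), and 4 of the list were higher with array medians set equal. Of 10 endothelial markers 0 rose and 1, TIE1, fell (-0.33; 0 and 1 adjusted over the list alone), and PECAM1, whose 2 probe sets differ in sign, was at 0.16 with both group means below the background level (camera adjusted p = 0.43, median -0.024). PECAM1 passed after a further quantile normalization (0.25, limma adjusted p = 0.017), with array medians set equal (0.26, 0.016) and with array weights (0.23, 0.020). TIE1 lost the threshold with array medians set equal and without replicate 2 of either group, PARP-2 shRNA replicate 3 or scrambled shRNA replicate 1 (limma adjusted p = 0.051 to 0.066). Of 7 cholangiocyte markers 0 rose and 2 fell, also adjusted over the list alone, with keratin 7 (KRT7) at -1.22 and osteopontin (SPP1) at -0.68 (camera adjusted p = 0.083, median -0.0067). This list passed without PARP-2 shRNA replicate 2 (camera adjusted p = 0.048) and after a further quantile normalization (0.047).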

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

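The results here concern probe sets left out of the gene comparison, tested in 1 limma fit over all 33297 probe sets with 3 arrays per group, and each is listed because data outside the gene comparison carried a signal. Of the 12083 probe sets that were not in the annotation table, 220 were higher and 1144 lower with the PARP-2 hairpin, with a median log2 difference of -0.057 and a median log2 level of 6.22. Of the 1754 probe sets annotated to several gene symbols, 56 were higher and 215 lower, with a median of -0.024. The 19460 probe sets with 1 symbol gave 1286 higher and 1125 lower in the same fit, with a median of 0.017. No explanation for the difference between these classes was tested.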

How the results depend on the processing

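No alternative here was chosen after the result was seen. PARP2 stayed lower and past the threshold in limma under its 15 alternatives (-0.70 to -0.59, adjusted p from 2.35e-07 to 0.0026). Of the 3348 calls, 2992 were kept after a further quantile normalization, 2761 with array medians set equal and 1917 to 2445 with 1 array left out. Higher genes, 1877 as reported, numbered 2868 after quantile normalization, 4434 with equal medians, 145 at 1.5-fold, 721 at an adjusted p under 0.01 and 1138 with a variance per gene alone. Lower genes, 1471 as reported, numbered 898 with equal medians, 290 at 1.5-fold, 728 at an adjusted p under 0.01 and 839 with a variance per gene alone. Leaving out 1 array gave 1027 to 1474 higher and 934 to 1234 lower, with fewer samples, and 16 to 19 lists. Over all probe sets 2484 probe sets, not genes, were lower: 1125 with 1 symbol, and 215 with several symbols and 1144 unannotated, which the gene fit does not hold. Of 16 lists, 0 passed with an estimated correlation (9 of 38 at unadjusted p under 0.05) and 26 of 38 passed fry, which does not compare a list with other genes. The estimated correlation was below the preset 0.01 for fatty acid synthesis (-0.0054), cholesterol efflux (-0.0065), bile acids (-0.011) and base excision repair (-0.0057). Their unadjusted camera p still rose, for fatty acid synthesis from 1.31e-05 to 0.0086. Correlation between genes therefore does not account for the loss of these lists. The other lists that had passed had estimates above 0.01. The stricter thresholds and fewer arrays lower counts by construction. Equal array medians raise the difference of every gene by the same amount, so more rises and fewer falls follow by construction too. The cause of the remaining changes was not tested.

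The replicate numbers did not pair the arrays, since deviations of same-numbered arrays correlated at -0.099, 0.10 and -0.076. With the number as a replicate block, 1258 genes were higher, 1172 lower and 2318 calls kept, 16 lists passed and PARP2 was at -0.68 (limma adjusted p = 0.0026).

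Of 123 named genes past the threshold, 109 passed in all 6 fits with 1 array left out. Most were named for a large difference or a small p on these same arrays, so that share does not describe all 3348 calls. Among the named genes the threshold was lost by 6 under the replicate block, 7 over all probe sets and 5 with array medians set equal. Of the 3348 calls 1 turned its sign with the mean of a gene's probe sets and 0 under the other settings that refit all genes. Among named genes and lists, direction turned for ones that did not pass. With equal medians the turn of ABCA1 follows from the amount added to every gene, and the cause of the other turns was not tested. ABCA1 was at 0.082 with equal medians and -0.037 to 0.0060 with 1 array left out, and PECAM1 at -0.13 as the mean of its probe sets. For 6 lists the direction of camera turned, with these medians: PARP family -0.0061 (all probe sets) and -0.027 to -0.0063 (1 array left out); sterol uptake 0.035 (quantile), 0.14 (equal medians), 0.037 (block) and 0.022 to 0.055 (1 array left out); homologous recombination 0.064 (quantile), 0.0040 (median-level filter) and -0.026 to 0.048 (1 array left out); xenobiotic metabolism 0.011 (median-level filter); heat shock 0.064 (quantile) and -0.013 to 0.058 (1 array left out); reference genes 0.0010 (quantile), -0.0085 (median-level filter, ranks) and -0.018 to 0.0044 (1 array left out). For the 5388 genes at or below the background level, signal over background limits what can be seen.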

Other observations

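The gene lists of this part and the tests of MAPK output and TGF-beta targets were chosen after the result was seen; the tests of array brightness, SREBP-2, fibroblasts, chromosomes and splits were not. Adjusted p-values of the added lists were taken over 43 lists, the 38 fixed ones included, and with an estimated correlation none of the added lists passed, as none of the fixed ones did (9 of 38 fixed lists at an unadjusted p under 0.05). Of 23 measured genes of integrins, laminins and focal adhesion, 1 rose and 14 fell, with a median log2 difference of -0.25. The laminin chain LAMB3 was at -1.57, the integrin subunits ITGA5 and ITGB4 at -0.91 and -0.79 and the adaptor TNS1 at -0.66, while TLN1 was at 0.24. The camera adjusted p was 4.57e-08, and the adjusted p was 0.097 with an estimated correlation. Without ITGA3, which had prompted the list, 13 of 22 genes fell with a median of -0.25.

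Of 14 TGF-beta targets 1 rose and 8 fell, with a median of -0.38. PMEPA1 was at -1.48, LTBP2 at -1.10, BHLHE40 at -0.92, SKIL at -0.90 and the inhibitory SMAD7 at -0.50, while CCN2 rose by 0.30 and COL4A1 and COL4A2 were at 0.015 and -0.013. The camera adjusted p was 9.31e-07, and the adjusted p was 0.084 with an estimated correlation. Of 18 genes of amino acid catabolism 6 rose and 0 fell, with a median of 0.17, including MAT1A at 0.66 and AGXT at 0.51 (camera adjusted p = 5.50e-05; adjusted p = 0.084 with an estimated correlation). Of 21 YAP and TEAD targets 3 rose and 8 fell (camera adjusted p = 0.044, and adjusted p = 0.30 with an estimated correlation). Without CCN1 and TGFB2 that list did not pass (camera adjusted p = 0.28). The microRNA gene MIR21, left out by the naming rule and named after its value was seen, was at -1.80 (SE 0.19, limma adjusted p = 7.31e-04).

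The number of genes past the threshold was compared with other groupings of the arrays. Of the 10 ways to split 6 arrays into 3 and 3, only 1, the real one, gave 3348 genes in limma, and the highest of the others gave 0 (242 to 862 genes at an unadjusted p under 0.05, against 5821 for the real split). With 10 splits a share under 0.05 cannot be reached. Each of the other splits also mixes arrays of both groups, so the difference between the groups widens its spread. Their low counts are therefore no measure of chance.

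The higher levels of cholesterol biosynthesis genes were weighed against a shift that depends on a gene's brightness. The list's median of 0.30 stood at percentile 100 of 10000 random lists matched on mean value, whose central 95% ended at 0.14, which argues against that shift. Higher activity of SREBP-2 is a candidate explanation that stays open. Of 3 other sterol-regulated genes 1 passed, STARD4 at 0.34, while TMEM97 was at 0.13 and INSIG1, near the background level, at -0.13, for a median of 0.13. An effect of PARP-2 loss and an effect of the hairpin on other transcripts both stay open, as untested.

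The 290 genes lower by 1.5-fold or more were weighed against fibroblasts in the scrambled cultures and against a chromosomal change. COL1A1, COL1A2, COL3A1 and DCN had a median difference of -0.0062, with 3 of them above the background level in the scrambled arrays. COL1A1 fell by 0.34 and 4 of 12 genes on the fibroblast list fell, but fibroblasts would lower all their abundant transcripts. On the spread between these samples, which may be technical, COL1A2 (95% interval -0.16 to 0.30) and COL3A1 (-0.19 to 0.081) exclude a fall of 1.5-fold. The lowest median of any autosome was 0.0046, which argues against loss or gain of a whole chromosome but does not cover a change in part of one. Chromosome 12 held 29 such genes among 982 (permutation p = 0.018 for the largest excess, over 10000 random draws of genes). Chromosome 1 (46 among 1866) and chromosome 20 (16 among 535) had the next largest excesses. Lower TGF-beta signalling is a candidate, and its targets stood at percentile 0 of matched lists (camera adjusted p = 0.084 with an estimated correlation). Lower MAPK output is another, at percentile 0.2 without EGR1 and FOSL1 (15 genes, 2 up, 5 down). Its camera adjusted p was 0.019, and 0.33 with an estimated correlation. The matched lists take no account of correlation between genes. A shifted list median does not show that a pathway accounts for the 290 falls. Of the 15 MAPK genes only IER3 (-0.59) fell by 1.5-fold or more. Of the 14 TGF-beta targets only PMEPA1, LTBP2, BHLHE40 and SKIL did. Against lower TGF-beta signalling, CCN2 rose by 0.30 and COL4A1 and COL4A2 were at 0.015 and -0.013, while 8 of 14 targets fell. Against lower MAPK output, the MAPK-induced genes ETV4 and ETV5 rose by 0.26 and 0.46 and DUSP6 was at 0.057. Both remain hypotheses found and tested on the same arrays.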
